A study of Homo sapiens with 6 samples.

How the data were processed

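The series holds 6 RNA libraries of HEK293 cells, an established human embryonic kidney line that was grown here in suspension. Per the labels and the design text, 3 libraries came from cultures transfected with a pair of plasmids and a polymer reagent to make adeno-associated virus, and 3 from cultures that received buffer in place of DNA and reagent. Cells were taken 18 h after transfection, untransfected cultures at the same time. Per the labels' protocols, total RNA was extracted with an acid phenol reagent, libraries were made with a stranded total RNA kit (TruSeq Stranded Total RNA), and paired-end reads of 75 nt were sequenced on a NextSeq system. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

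The authors deposited 1 table of TPM values (transcript abundance scaled to a fixed total per library), with an Ensembl ID and a symbol per row. Per the submitters' processing notes, STAR and the GRCh38 build were used, with no version or role given. The counting tool, its strand setting, the annotation, the gene lengths and any filter on genes are not given in the sources used here. In the deposited table the TPM values of each library sum to the same total over distinct IDs, so the values are shares of the listed genes and keep no sequencing depth. Depth is therefore unknown, and no counting interval or detection floor was computed. A rise of abundant genes lowers the TPM of all others in the same library.

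The table had 18298 rows and 18164 distinct Ensembl IDs. There were 126 IDs listed under 2 or more symbols, with the same values in each row, and each was kept once. Of the IDs, 18139 matched a table of gene names and 17706 were placed on GRCh38 with GENCODE release 29, which also gave gene type, exon length and GC content. There were 1668 IDs with no symbol, which stayed in the tests but are not named. The table used here held 0 features named as plasmid, adeno-associated virus or adenovirus sequence.

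Genes were kept when TPM was at least 1 in at least 3 of the 6 libraries, which left 16500. A gene under 1 TPM throughout a group was therefore tested only if all 3 libraries of the other group reached 1. For such genes a difference between groups was a condition of the test, for example CGAS, CXCL11, ISG20, HSPA6, ABCC2, ITGAM and ALB. Transfected and untransfected libraries were compared with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with group as the only term, a variance prior that follows mean expression, and two-sided p-values adjusted by the Benjamini-Hochberg method over the genes kept. A gene was called at an adjusted p under 0.05. Fold changes are differences of mean log2(TPM + 1), transfected minus untransfected, with the standard error of the fit, and this scale understates the change of genes with low TPM. Group levels are mean TPM ± SD over 3 libraries.

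Before the data were examined, 30 gene lists with 1008 members were fixed, of which 877 were in the table. They covered innate sensing, interferon and cytokine genes, stress responses, cell cycle, repair, histones, lipid and energy metabolism, ribosomes, virus entry factors and markers of leukocytes, hepatocytes and fibroblasts. Each list with at least 3 tested members was compared with all other genes by limma's camera with the inter-gene correlation preset at 0.01, adjusted over 28 lists. Camera with a correlation estimated from the data, and fry, which asks whether members move on balance in the same direction, were run beside it. Over each list, calls were also counted with p-values adjusted over the list alone.

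The genes named were chosen by a rule fixed beforehand. It took the 8 largest rises and the 8 largest falls among called genes with a mean TPM of at least 5 in the higher group and no overlap between groups, skipping features without a proper name. It also took from each list the 2 called members that changed most in the direction most members took, and the 1 that changed most in the other direction. Some genes that the rule took are not reported here. Where a gene outside this rule is named, it was chosen after its values were seen.

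Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter or a minimum TPM of 5, and a replicate block. Scaling alternatives were median-of-ratios scaling, quantile normalization, and TPM recomputed without mitochondrial, small RNA and histone genes. The others were a variance prior without trend or with robust fitting, library weights, an adjusted p under 0.01, limma's treat against a fold change of 1.5, and leaving out each library in turn. A loess correction of each library for GC content (span 0.3), a fit on protein-coding genes only and TPM recomputed without mitochondrial genes alone were added after seeing the data. The procedure was tested on simulated values for 16500 genes with 200 of them changed. It recovered 35, 45, 46 and 50 of 50 genes changed 1.25-, 1.5-, 2- and 4-fold, made 8 false calls (4.35% of calls), and called 0 of 28 unchanged lists. The simulated genes were independent of each other, so the last count says nothing of lists whose genes vary together. The share of genes changed was far below the 70.2% called in the data, so the rate of false calls may not carry over.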

Results

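Gene expression was measured by total RNA sequencing in HEK293 suspension cells 18 h after transfection for adeno-associated virus production, with untransfected cultures as the reference. Adeno-associated virus is a small DNA virus used as a gene therapy vector, which producer cells make from transfected plasmids. Each group had 3 libraries. The comparison asks how the transcriptome of the producing culture differs from that of the untreated culture. Plasmid and reagent were given together, so their effects are not separated. Values are TPM, from which depth is unknown. Between 16331 and 16368 IDs reached 1 TPM in a transfected library, against 15806 to 15859 in an untransfected library. Mitochondrial genes took 27.5% ± 0.574 of TPM in transfected and 33.1% ± 0.494 in untransfected libraries (SD, n = 3 per group).

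The transcriptomes of the 2 groups separated widely. Of 16500 genes kept, 11578 were called by limma at a Benjamini-Hochberg adjusted p under 0.05, 7156 of them higher and 4422 lower after transfection. A change of at least 2-fold was found for 1107 genes, 870 higher and 237 lower, so most called changes were under 2-fold. The first principal component held 88.9% of the variance and split the groups. Pearson correlations of log2(TPM + 1) across genes were 0.995 to 0.997 between libraries of the same group and 0.955 to 0.958 between groups. Groups did not overlap for 74.0% of genes kept, where 10% would be met by chance. The share of calls that were higher, 61.8%, depended on scaling. It was 50.6% with median-of-ratios scaling, 47.5% with quantile normalization, 50.0% with TPM recomputed without mitochondrial, small RNA and histone genes, and, in alternatives added after seeing the data, 45.4% with the GC correction and 49.7% with TPM recomputed without mitochondrial genes alone. Relative to the fit reported here, the median gene moved by -0.10 (log2) with either recomputed TPM, -0.12 with quantile normalization and -0.14 with the GC correction. Where a list median is given, its value relative to the median gene, which stood at 0.09, follows.

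Among protein-coding genes, the largest rises named by the rule were those of DNAH17, an axonemal dynein heavy chain, EGR1, an immediate-early zinc finger transcription factor, and DHRS2, a short-chain dehydrogenase. EGR1 (ENSG00000120738) rose from 11.97 ± 1.72 to 203.7 ± 10.5 TPM, a log2 fold change of 3.99 ± 0.09 (SE, n = 3 per group; limma adjusted p = 1.04e-07). DHRS2 (ENSG00000100867) rose from 3.02 ± 0.188 to 59.2 ± 3.98 TPM and DNAH17 (ENSG00000187775) from 1.43 ± 0.102 to 47.7 ± 1.30 TPM, log2 fold changes of 3.90 and 4.32. INSIG1 (ENSG00000186480), which holds the sterol-sensing SREBP complex in the endoplasmic reticulum, had the largest log2 fall among the genes kept, from 659.6 ± 5.09 to 138.1 ± 1.26 TPM (log2 fold change -2.25 ± 0.02, limma adjusted p = 7.83e-09). IRS4 (ENSG00000133124), an insulin receptor substrate, fell from 1213 ± 17.6 to 336.1 ± 11.7 TPM. HMGCS1 (ENSG00000112972), the cytosolic synthase of the mevalonate pathway, fell from 666.2 ± 17.9 to 200.1 ± 9.75 TPM. The transporter family member MFSD3 and the small GTPase RAB26 had log2 fold changes of -1.86 and -1.96.

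The other genes that the rule took for the largest changes were non-coding. LARP4B-DT rose from 1.51 ± 1.12 to 94.2 ± 9.69 TPM, CCDC13-AS2 from 0.373 to 48.7, TM4SF18-AS1 from 0.873 to 53.4, LINC01647 from 0.320 to 21.5 and the pseudogene XRCC6P1 from 0.457 to 16.7. The falls were LINC02361 from 6.95 to 1.03 TPM, NALT1 from 9.49 to 1.99 and LINC02593 from 14.6 to 3.34. These values are uncertain where genes share reads or overlap, since the strand setting of the counting is not given in the sources used here. CCDC13-AS2 overlaps CCDC13 and TM4SF18-AS1 overlaps TM4SF18 on the opposite strand, both not analysed here. DNAH17 overlaps PGS1, which had a log2 fold change of 0.16 ± 0.03. XRCC6, of which XRCC6P1 is a processed copy, changed by 0.26 ± 0.03. LARP4B, 1321 bases from LARP4B-DT, rose by 0.46 ± 0.04, and SAMD11, 2912 bases from LINC02593, had a log2 fold change of -1.33 ± 0.07.

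In GENCODE release 29 on GRCh38, EGR1 spans bases 138465490 to 138469315 of chromosome 5, DHRS2 bases 23630115 to 23645639 of chromosome 14 and DNAH17 bases 78423697 to 78577394 of chromosome 17. INSIG1 spans bases 155297776 to 155310235 of chromosome 7, HMGCS1 bases 43289395 to 43313512 of chromosome 5 and IRS4 bases 108732482 to 108736409 of chromosome X. LARP4B-DT lies on chromosome 10 at bases 933026 to 942743 and CCDC13-AS2 on chromosome 3 at bases 42770612 to 42773635.

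**Figure D1:**
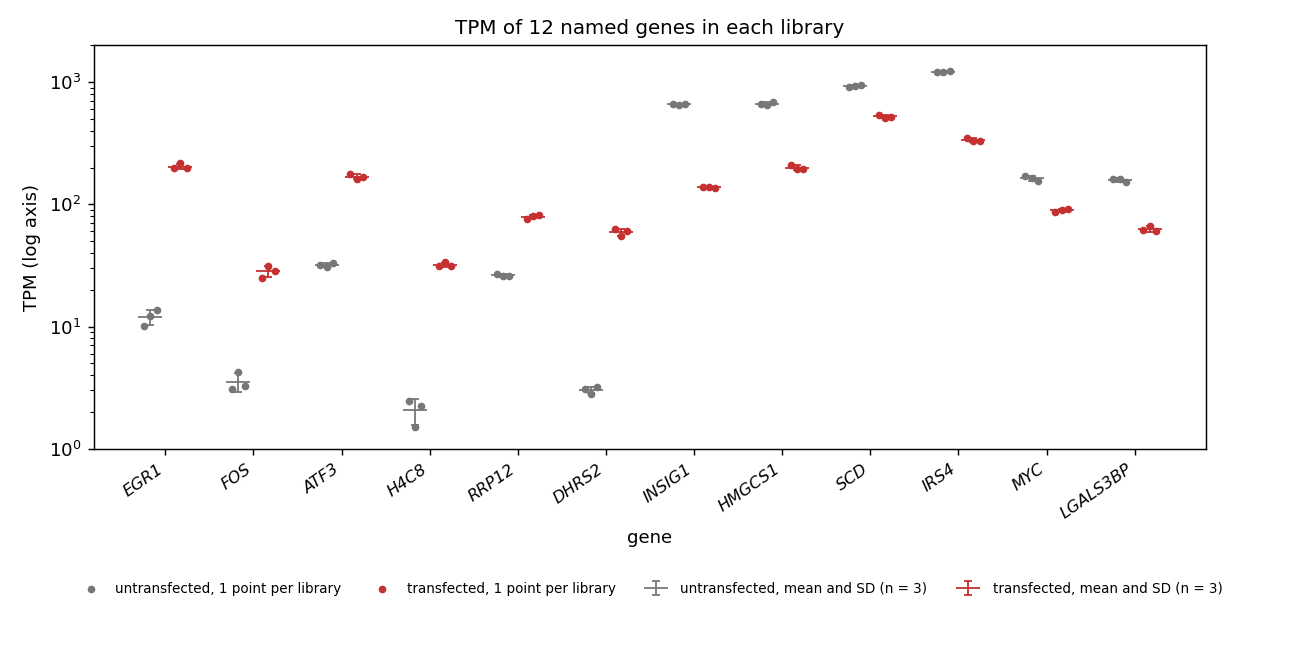
TPM (log axis) of 12 named genes in each library, with 1 point per library and the mean and SD of each group (n = 3). In each of these genes all transfected libraries lie on the same side of all untransfected ones, for example EGR1 at 203.7 against 11.97 TPM and INSIG1 at 138.1 against 659.6 TPM.

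Of 28 gene lists tested with camera, 11 were called, 5 toward higher and 6 toward lower expression. With an estimated correlation only cholesterol synthesis and uptake stayed called. Of the 17 lists that camera did not call, fry called 13, which does not compare a list with other genes. For lists, each range over alternatives pools camera under the other settings, camera with an estimated correlation, and fry. Fry was run only on the fit reported here, and either end of a range may come from fry or from the estimated correlation. In the 9 splits of the 6 libraries that mix the groups, camera with the preset correlation still called between 6 and 9 lists. Each such split keeps part of the group difference, so these calls are not a rate of false calls. The counts of called members come from limma and do not rest on the preset correlation. They are to be read against all genes kept, of which 70.2% were called, 7156 of 16500 higher and 4422 lower. For example, the counts of endoplasmic reticulum chaperones, p53 targets and apoptosis regulators lay near these shares. The share of ribosomal protein genes called higher was below that of all genes. Counts adjusted over the list alone are given where they differ. For 24 of the 30 lists they were the same as over all genes.

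Cholesterol genes fell together. Of 25 measured genes of cholesterol synthesis and uptake, 22 fell, 2 rose and 1 did not pass, with the same counts adjusted over the list alone. The falls included INSIG1 and HMGCS1, with log2 fold changes of -2.25 ± 0.02 and -1.73 ± 0.04. PMVK, which acts after mevalonate kinase, rose by 0.37 ± 0.04 on the log2 scale and LPIN1 by 0.15, the latter not called higher with each other scaling or with the GC correction, and CYP51A1, at -0.09, did not pass. The summed TPM of the list was 1623 ± 14.8 after transfection and 3605 ± 20.2 without it. The list median was -0.86, or -0.96 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 7.19e-11, and adjusted p = 0.0408 with an estimated correlation). Over the 22 alternatives its adjusted p ranged from 1.15e-11 to 0.0408.

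Of 17 fatty acid synthesis genes, 11 fell and 5 rose. The rises were 1 with each other scaling and 0 with the GC correction, where 12 fell, and 2 without untransfected replicate 1 and 3 without transfected replicate 1, untransfected replicate 2 or untransfected replicate 3. The desaturases SCD and FADS2 fell by 0.82 and 0.81 on the log2 scale, SCD from 925.5 ± 18.5 to 523.8 ± 13.3 TPM. HSD17B12, a reductase of fatty acid elongation, rose by 0.32 ± 0.06, but was 0.08 with the GC correction (limma adjusted p = 0.279, range over alternatives 1.12e-04 to 0.279). The list median was -0.31, or -0.40 relative to the median gene, and camera gave an adjusted p of 0.00400 (adjusted p = 0.223 with an estimated correlation, range over alternatives 2.29e-05 to 0.223). In glycolysis 12 of 22 genes fell and 4 rose. PFKFB4, which sets fructose bisphosphate levels, and the aldolase ALDOC had log2 fold changes of -1.16 and -0.91, and the enolase ENO3 rose by 1.03. The camera adjusted p of glycolysis was 0.00648 (adjusted p = 0.414 with an estimated correlation, range over alternatives 0.00270 to 0.414).

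Replication-dependent histone genes, which are normally transcribed in S phase, rose without exception among the 29 tested, 28 of them at least 2-fold. H4C8 rose from 2.06 ± 0.504 to 31.9 ± 1.39 TPM and H4C5 from 3.30 ± 1.15 to 28.5 ± 6.49 TPM. Their summed TPM was 1290 ± 82.5 after transfection against 298.1 ± 14.3 without it (SD, n = 3 per group), a ratio of 4.33. Histone genes include near-identical copies, so values of single genes are uncertain where reads were shared. The list was fixed with 62 genes, and those without deposited values are not in this sum. The list median was 1.91, or 1.82 relative to the median gene, and camera gave an adjusted p of 3.87e-08 (adjusted p = 0.223 with an estimated correlation, range over alternatives 3.33e-11 to 0.223).

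Other cell cycle and genome maintenance genes changed less. Of 52 DNA replication genes, 35 rose and 6 fell, against 27 and 10 with median-of-ratios scaling, 26 and 14 with quantile normalization and 26 and 13 with the GC correction. CCNE2, a cyclin of S-phase entry, and the replication initiation factor MCM10 rose by 1.04 ± 0.04 and 0.92 ± 0.03, and the transcription factor E2F1 fell by 0.26 ± 0.04 on the log2 scale. The list median was 0.23, or 0.13 relative to the median gene. Its camera adjusted p was 0.00400, and it was not called with quantile normalization (adjusted p = 0.0818) or with an estimated correlation (adjusted p = 0.370, range over alternatives 2.89e-05 to 0.370). In DNA damage response and repair 28 of 39 genes rose and 4 fell (26 and 8 with median-of-ratios scaling), among them the recombination gene BRCA2 and the checkpoint mediator MDC1 with rises of 1.08 ± 0.05 and 1.02 ± 0.04, and the kinase gene CHEK2 with a log2 fold change of -0.40 ± 0.05. Camera gave an adjusted p of 0.00356 for that list (adjusted p = 0.404 with an estimated correlation, range over alternatives 4.02e-05 to 0.404). Of 40 mitosis genes, 23 rose and 3 fell, while with quantile normalization 14 rose and 13 fell and with the GC correction 9 rose and 18 fell. The list was not called (camera adjusted p = 0.0610, range over alternatives 1.32e-04 to 0.864), but was without transfected replicate 2 (adjusted p = 0.0484). HMMR and NDC80, a spindle and a kinetochore gene, rose by 0.96 and 0.73, and CDCA3 had a log2 fold change of -0.41.

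**Figure D2:**
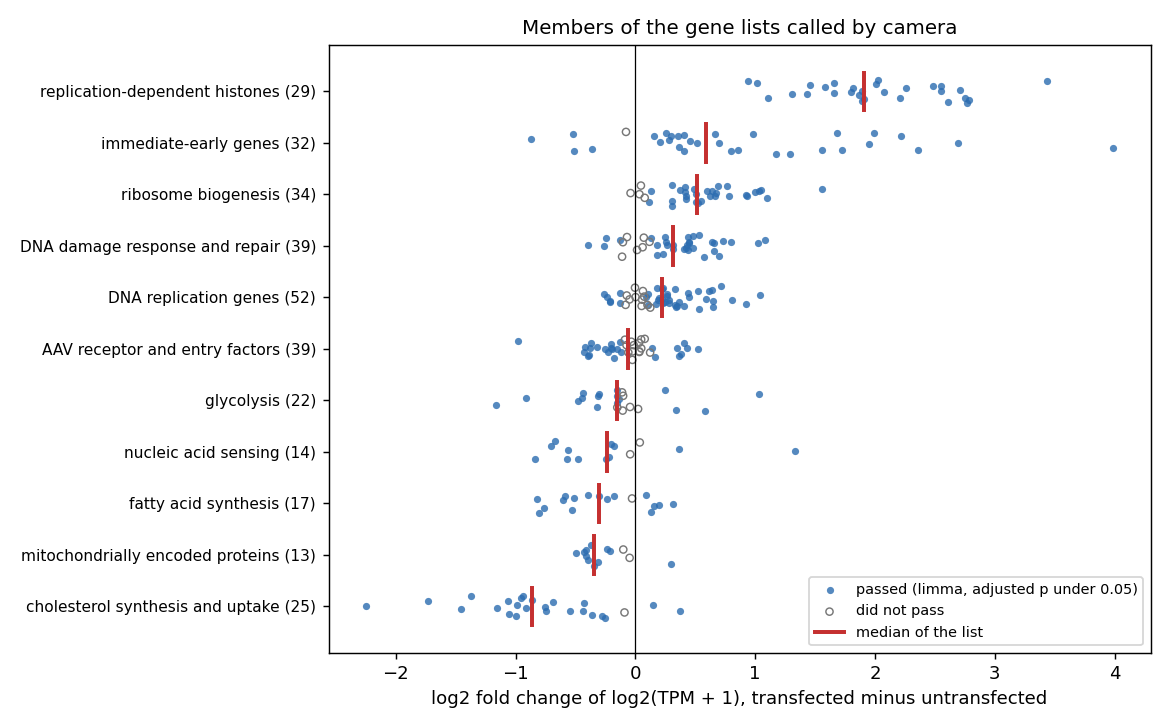
Log2 fold changes (transfected minus untransfected, log2(TPM + 1) scale) of the members of the 11 lists called by camera, with 1 point per gene, filled where the gene passed limma, and a bar at the list median. The number tested follows each name, and medians run from -0.86 for cholesterol genes to 1.91 for histones.

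Immediate-early genes, transcribed within minutes of a stimulus, were mostly higher at 18 h. Of 32 measured, 27 rose and 4 fell. Besides EGR1, FOS, a subunit of the AP-1 factor, rose from 3.54 ± 0.619 to 28.3 ± 3.13 TPM, and MYC, a growth-promoting transcription factor, fell from 163.7 ± 8.40 to 89.1 ± 2.25 TPM. The other falls were those of IER5, BTG2 and DUSP6, at -0.52, -0.51 and -0.36 on the log2 scale. The list median was 0.59, or 0.50 relative to the median gene (camera adjusted p = 0.00336, and adjusted p = 0.370 with an estimated correlation, range over alternatives 8.10e-06 to 0.370).

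Stress response lists were not called by camera. Among 34 targets of ATF4, the factor of the integrated stress response, 12 rose and 17 fell. ATF3, a stress-induced factor that the immediate-early list also holds, rose from 32.0 ± 1.06 to 168.3 ± 7.83 TPM, while DDIT4, an inhibitor of mTORC1, and the gluconeogenic gene PCK2 fell by 0.74 and 0.66 on the log2 scale. PPP1R15A, which restores translation after stress, rose from 56.1 ± 2.64 to 286.1 ± 13.7 TPM, and 4 members rose and 0 fell at least 2-fold. The median of this list was -0.12, or -0.22 relative to the median gene, and its mean 0.11. Camera set it below the other genes (adjusted p = 0.211). Fry, which asks whether the members move on balance one way, set it above 0 (adjusted p = 9.88e-04). The range over alternatives, camera and fry together, was 9.88e-04 to 0.730. Of 31 genes of endoplasmic reticulum chaperones and the unfolded protein response, 13 rose and 8 fell (camera adjusted p = 0.935), but more fell than rose with each other scaling and with the GC correction, as in 10 higher and 14 lower with median-of-ratios scaling. The falls were 4 without transfected replicate 2, untransfected replicate 1 or untransfected replicate 3. The fry adjusted p of this list was 0.00240 toward higher, and its range over alternatives, camera and fry together, was 0.00240 to 0.997. Its factor XBP1 and the co-chaperone DNAJC3 rose by 0.95 and 0.85, and SDF2L1 had a log2 fold change of -0.74. Of 25 cytosolic heat shock genes, 12 rose and 9 fell (camera adjusted p = 0.742), against 10 and 10 with median-of-ratios scaling and 10 and 13 with the GC correction. The fry adjusted p of these genes was 9.75e-04 toward higher, and their range over alternatives, camera and fry together, was 9.75e-04 to 0.901. Among these CHORDC1, an HSP90 partner, rose by 1.12 ± 0.06 and HSPA6, an inducible HSP70, by 0.96 ± 0.19, and the small heat shock gene HSPB1 had a log2 fold change of -0.47.

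Of 28 p53 targets, 14 rose and 8 fell, and 9 fell adjusted over the list alone. The median of the list was 0.12, or 0.02 relative to the median gene and -0.004 with quantile normalization. Camera set it below the other genes (adjusted p = 0.935) and fry above 0 (adjusted p = 2.65e-04). The range over alternatives, camera and fry together, was 2.65e-04 to 0.995. GADD45A, a growth arrest gene, and the phosphatase gene PPM1D rose by 1.26 ± 0.08 and 1.00 ± 0.05, and FDXR, a mitochondrial reductase, had a log2 fold change of -0.93. Of 29 apoptosis regulators, 12 rose and 8 fell, with 13 higher adjusted over the list alone (camera adjusted p = 0.850), against 9 and 9 with median-of-ratios scaling and 7 and 11 with the GC correction. The initiator caspase gene CASP8 rose by 0.61 ± 0.05 and the pro-apoptotic gene BAX had a log2 fold change of -0.37. Of 24 NF-kB feedback and target genes, 13 rose and 6 fell (camera adjusted p = 0.475). The subunit gene NFKB1 and the inhibitor gene NFKBIB rose by 1.15 ± 0.04 and 1.12 ± 0.05, and TNFAIP2 had a log2 fold change of -0.93 ± 0.08.

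Innate immune genes moved in both directions. In nucleic acid sensing 10 of 14 genes fell and 2 rose. MAVS, the adaptor of the RNA sensors, fell from 52.5 ± 1.31 to 31.8 ± 2.13 TPM and the kinase gene IKBKE by 0.84 ± 0.10 on the log2 scale, whereas CGAS, the cytosolic DNA sensor, rose from 0.0633 ± 0.0416 to 1.68 ± 0.172 TPM. The other rise was that of EIF2AK2, a kinase activated by double-stranded RNA, at 0.36. Camera gave an adjusted p of 0.00747 (adjusted p = 0.294 with an estimated correlation, range over alternatives 2.83e-04 to 0.294). Of 36 interferon-stimulated genes, 13 rose and 13 fell (camera adjusted p = 0.233), against 10 and 15 with median-of-ratios scaling and 8 and 16 with the GC correction. The list had a median of 0.01, or -0.09 relative to the median gene, and a mean of -0.02, and camera set it below the other genes. ISG20, an RNA exonuclease gene, and IFIT2 rose by 1.06 ± 0.10 and 0.97 ± 0.10, and LGALS3BP, which encodes a secreted glycoprotein, fell from 158.1 ± 5.98 to 62.8 ± 3.13 TPM. Of 11 interferons, cytokines and chemokines tested, 7 rose and 1 fell (camera adjusted p = 0.307), against 6 and 2 without transfected replicate 2 and with median-of-ratios scaling. At a minimum TPM of 5 only 5 were tested, of which 2 rose and 0 fell. The list median of 0.65 then became 0.08 (camera adjusted p = 0.800). The fry adjusted p of this list was 0.00194 toward higher, and its range over alternatives, camera and fry together, was 0.00194 to 0.800. CXCL11 rose from 0.150 ± 0.156 to 2.51 ± 0.173 TPM and IL11 by 1.55 ± 0.15 on the log2 scale, and IL18 had a log2 fold change of -0.53. In antigen presentation by MHC class I, 5 of 16 genes rose and 7 fell, and 8 fell adjusted over the list alone (camera adjusted p = 0.233). With quantile normalization 2 rose and 8 fell. The peptidase gene ERAP2 and the proteasome activator PSME1 fell by 0.91 and 0.66 on the log2 scale. NLRC5, a transactivator of this pathway, rose by 0.41 ± 0.09, but was 0.19 with quantile normalization (limma adjusted p = 0.0901, range over alternatives 0.00143 to 0.0901).

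Genes of ribosome biogenesis rose in 30 of 34 cases and fell in 0. RRP12, a factor of ribosome assembly, rose from 26.3 ± 0.711 to 79.3 ± 2.48 TPM and WDR43 from 117.7 ± 5.70 to 253.5 ± 3.77 TPM. The list median was 0.52, or 0.42 relative to the median gene (camera adjusted p = 2.55e-07, and adjusted p = 0.346 with an estimated correlation, range over alternatives 2.95e-08 to 0.346). Of 78 cytosolic ribosomal protein genes, 30 rose and 0 fell, or 23 higher adjusted over the list alone, while 13 rose and 13 fell with median-of-ratios scaling, 17 and 10 with quantile normalization, 12 and 14 with either recomputed TPM and 9 and 25 with the GC correction. RPL6 and RPL10A rose by 0.33 and 0.32, or by 0.22 and 0.21 with the recomputed TPM, and RPL6 by 0.12 with the GC correction. The list was not called (camera adjusted p = 0.178, range over alternatives 0.0155 to 0.858), but was without transfected replicate 1 (adjusted p = 0.0155).

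Of 13 mitochondrially encoded proteins, 10 fell and 1 rose, but 6 fell without a filter, 7 to 10 leaving out each library, and 2 fell and 2 rose with quantile normalization, which sets the most abundant genes to the same level. MT-ATP6, a subunit of the ATP synthase, and MT-ND4L, a subunit of complex I, fell by 0.50 ± 0.08 and 0.43 ± 0.07 on the log2 scale, and MT-ND1 of complex I rose by 0.29 ± 0.06. MT-ATP6 and MT-ND4L did not pass with quantile normalization (-0.07 for both), nor MT-ND1 with the GC correction (0.10). Their summed TPM was 257702 ± 6888 after transfection and 320572 ± 4989 without it. Camera gave an adjusted p of 0.00747 (adjusted p = 0.445 with an estimated correlation and 0.864 with quantile normalization, range over alternatives 0.00116 to 0.864). MT-RNR2, a mitochondrial ribosomal RNA, rose from 6603 ± 105.7 to 11691 ± 437.1 TPM. The other, MT-RNR1, rose from a mean of 2646 to 4396 TPM, with transfected libraries spread from 3661 to 5222. Whether the ribosomal RNA changed in the cells or in the making of the libraries was not tested. Nuclear-encoded oxidative phosphorylation was not called (camera adjusted p = 0.178), with 15 of 75 genes higher and 17 lower, or 14 and 16 adjusted over the list alone. NDUFA11 and NDUFB2 of complex I fell by 0.57 ± 0.12 and 0.34 ± 0.05 on the log2 scale, and NDUFV2 of the same complex rose by 1.22 ± 0.11. With median-of-ratios scaling this list was called, with 5 genes higher and 37 lower (camera adjusted p = 0.00999, range over alternatives 0.00416 to 0.795), and so it was with the other scalings and the GC correction.

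Of 39 adeno-associated virus receptor and entry factors, 17 fell and 8 rose. SLC35B2, the sulfate donor transporter needed for heparan sulfate, fell from 71.2 ± 3.37 to 35.7 ± 4.66 TPM and the protease gene FURIN by 0.43 ± 0.04 on the log2 scale, and COG4 of the Golgi tethering complex rose by 0.52 ± 0.03. KIAA0319L, the main receptor, fell by 0.17 ± 0.05 on the log2 scale. The list was called at a camera adjusted p of 0.0490 (adjusted p = 0.456 with an estimated correlation, range over alternatives 0.00813 to 0.456). It was not called at a minimum TPM of 5 (adjusted p = 0.0507), with library weights (0.0531), in protein-coding genes only (0.0789), or without transfected replicate 1 (adjusted p = 0.0571), untransfected replicate 1 (0.0589) or untransfected replicate 2 (0.0543).

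The remaining lists were not called by camera. Of 43 lysosome and autophagy genes, 15 rose and 16 fell (adjusted p = 0.178), against 12 and 24 with median-of-ratios scaling, 11 and 25 with quantile normalization and 12 and 25 with the GC correction. The median was -0.04, or -0.13 relative to the median gene, and the mean 0.01, and camera set them below the other genes. CTSA, a lysosomal carboxypeptidase, fell by 0.81 ± 0.09 on the log2 scale and the factor TFE3 rose by 1.33 ± 0.03. Of 22 NRF2 and oxidative stress genes, 6 rose and 9 fell (camera adjusted p = 0.163). HMOX1, which degrades heme, fell by 0.96 ± 0.07 on the log2 scale, and the export pump gene ABCC2 rose by 0.66. Of 20 hypoxia targets, 5 rose and 7 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.233), and 4 rose and 13 fell with the GC correction. PFKFB4 is also on this list, NDRG1 had a log2 fold change of -0.61, and ANKRD37 rose by 1.01 ± 0.13. Of 5 metallothionein and zinc response genes, 4 rose (camera adjusted p = 0.278), but 2 without untransfected replicate 3, with each other scaling and with the GC correction. The rises included the zinc exporter SLC30A1 and MT2A at 0.54 and 0.52.

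Of 4 fibroblast markers tested, 3 fell (camera adjusted p = 0.115), among them the transcription factor TWIST1 and the collagen gene COL1A1 with log2 fold changes of -0.32 and -0.23. Too few leukocyte and hepatocyte markers were tested for camera, 2 of 4 and 1 of 3 with deposited values. The leukocyte markers ITGAM, an integrin, and CD8A, a T cell coreceptor, rose from 0.0233 to 1.64 and from 1.29 to 2.90 TPM. The hepatocyte marker ALB, serum albumin, rose from 0.0367 ± 0.0351 to 1.16 ± 0.169 TPM, with 1 untransfected library listed at 0. ITGAM and ALB were under 1 TPM in every untransfected library and were tested only because all 3 transfected libraries reached 1. Their rise was thus a condition of the test.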

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

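The tests with the GC correction, with protein-coding genes only and with TPM recomputed without mitochondrial genes alone were chosen after seeing the data. Of 1849 values of named genes under 20 alternatives, 1844 kept their direction and their call, 5 kept the direction without passing, and 0 reversed. With a pseudocount of 0.1 the log2 fold changes of 8 of them, all with low TPM, moved by over 1.5 times, for example ALB from 1.05 to 3.23 and CGAS from 1.33 to 3.47. Quantile normalization moved 8 by as much, among them PMVK from 0.37 to 0.23 and E2F1 from -0.26 to -0.43, and the GC correction 10, among them SLC30A1 from 0.54 to 0.30 and CASP8 from 0.61 to 0.40 (the cause was not tested). The count of called genes stayed within 1.5 times of 11578 except with treat, whose minimum change leaves 1775 (1322 higher, 453 lower). The count with at least a 2-fold change, 1107 of 16500 genes, was 1846 with a pseudocount of 0.1. It was 726 of 12359 at a minimum TPM of 5 and 619 of 12961 in protein-coding genes only, so in both of these the share fell as well. By direction, 870 higher and 237 lower became 1375 and 471 with that pseudocount, 574 and 411 with quantile normalization, 569 and 271 with the GC correction, 690 and 337 with median-of-ratios scaling, 817 and 417 with TPM recomputed without mitochondrial genes alone, and 814 and 415 with TPM recomputed without mitochondrial, small RNA and histone genes (the cause was not tested). Leaving out each library in turn gave 10689 to 11408 called genes and 1083 to 1118 with a 2-fold change. The share on the first principal component, 88.9%, was 87.7% with a pseudocount of 0.1, 88.2% without a filter, 92.2% at a minimum TPM of 5, 88.1% with quantile normalization, 88.0% with recomputed TPM, and 89.0% to 90.3% leaving out each library.

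Of the list tests under alternatives, 547 kept their direction and side of the threshold, 18 lost and 18 gained the call, and 30 took the other direction, 28 of them in lists not called either way. Fry gave the opposite direction to camera for ATF4 targets (median -0.12, mean 0.11, fry adjusted p = 9.88e-04) and p53 targets (median 0.12, fry adjusted p = 2.65e-04), and, with no call, for oxidative phosphorylation (median -0.0142) and lysosome (-0.0419). Camera itself set the endoplasmic reticulum chaperones below the other genes, with medians of -0.0862 with median-of-ratios scaling, -0.121 with quantile normalization, -0.0939 and -0.0960 with the recomputed TPM, -0.103 with the GC correction and 0.0189 with a replicate block. It did so too without transfected replicate 1 or untransfected replicate 2 (medians 0.00176 to 0.0424 leaving out each library). Ribosomal proteins changed likewise (-0.00871 with median-of-ratios scaling, -0.0162 and -0.0183 with the recomputed TPM, -0.0586 with the GC correction), as did apoptosis regulators (0.00454 with median-of-ratios scaling, 0.00462 with quantile normalization, 3.47e-04 and -0.00423 with the recomputed TPM, -0.0410 with the GC correction) and mitosis genes (-0.0637 with the GC correction). P53 targets went above the others (0.133 without a filter, 0.0156 with median-of-ratios scaling, -0.00383 with quantile normalization, 0.0512 and 0.00545 with the recomputed TPM, 0.0528 with the GC correction, 0.116 in protein-coding genes), also without transfected replicate 3 (0.115 to 0.137 leaving out each library). The cause was not tested. The ribosomal protein list was called without transfected replicate 1 (camera adjusted p = 0.0155) and the mitosis list without transfected replicate 2 (0.0484). TPM recomputed without mitochondrial, small RNA and histone genes leaves the histone and mitochondrial lists untested, and TPM recomputed without mitochondrial genes alone the latter.

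Replicate numbers are shared by the groups, but same-numbered libraries did not deviate together (correlations -0.04, 0.04 and -0.04 for numbers 1, 2 and 3), and only transfected replicate 2 correlated best with its own number. With a replicate block 11284 genes were called (6998 higher, 4286 lower). TPM keeps no depth, so the precision of low values cannot be judged from the table.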

Other observations

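The comparison of gene families, the trend with GC content, and the tests on the mitochondrial share, on S phase and on other splits for genes called were chosen after the result was seen, and the test on the mitochondrial share replaced others, of which 1 had its outcome fixed by centring and 1 also removed other genes. The genes that follow lie outside the fixed lists and were chosen after their values were seen. AMH, a gonadal hormone, rose from 8.44 ± 1.10 to 95.3 ± 9.31 TPM, STMN4, a neuronal stathmin, by 2.80 on the log2 scale, and MEIOSIN, a meiosis factor, from 2.94 ± 0.251 to 29.3 ± 1.69 TPM (limma, n = 3 per group). Among the falls, the BMP target genes ID1, ID2 and ID3, inhibitors of differentiation factors, had log2 fold changes of -1.50 ± 0.10, -1.30 ± 0.05 and -1.45 ± 0.09.

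Families of protein-coding genes that share a symbol root were compared after seeing the data, over 83 roots. Of 434 ZNF zinc finger genes, 295 rose and 43 fell, among them ZNF239 from 20.6 ± 1.59 to 62.6 ± 2.26 TPM. Their median was 0.34, or 0.23 with median-of-ratios scaling and 0.17 with the GC correction (camera adjusted p = 6.36e-05, and adjusted p = 0.615 with an estimated correlation). Nucleoporins (NUP) rose in 19 of 22 cases and fell in 0, and DDX helicases rose in 25 of 32 and fell in 3, with camera adjusted p of 0.00511 and 0.0132 and again adjusted p = 0.615 with an estimated correlation for both. Their medians were 0.30 and 0.36, or 0.12 and 0.20 with the GC correction. Called toward lower expression only with the GC correction were the TBC1D, TSPAN and RAB families (camera adjusted p = 0.0367, 0.0367 and 0.0425). Median log2 fold change fell with GC content, from 0.21 in 2531 genes of up to 40% GC to -0.17 in 2156 genes above 60%.

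More genes were called higher than lower, 61.8% of calls. With TPM recomputed without mitochondrial genes alone, over the same other genes, which scales each library to the same total, the share was 49.7%. The share of TPM outside the mitochondrial genome rose by 0.12 on the log2 scale, against 0.09 for the median gene. The recomputation lowers the other genes by up to about 0.12 on that scale. Nearly equal numbers of rises and falls thus follow from these values, so the 49.7% is no separate test. A lower mitochondrial share combined with TPM scaling may account for the excess among all calls, but 817 higher against 417 lower stayed at 2-fold or more with that TPM. These values cannot tell less mitochondrial RNA from more of all other RNA, since TPM holds only shares. Whether the mitochondrial share changed in the cells or in the libraries was not tested.

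Long non-coding genes and pseudogenes rose at least 2-fold more often than protein-coding genes, 11.3% of 2954 (exact 95% interval 10.2 to 12.5) against 3.53% of 12961. Falls of that size were seen in 2.06% of them against 1.24%. By class, 2.53% of 2099 long non-coding genes fell so, but only 0.94% of 855 pseudogenes. Low expression would give a like share of rises in protein-coding genes matched on mean TPM, which was 6.08%. Reads of overlapping protein-coding genes would leave few rises in non-coding genes that overlap none, where the share was 12.6% (10.9 to 14.4). After the GC correction the share was 8.23% (7.26 to 9.28), against 2.43% in protein-coding genes. These values argue against each of the 3 as the whole cause, while low expression and GC content may each hold part of it. The intervals take genes as independent and hold no spread between libraries, so they may be too narrow. No biological explanation was tested.

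The 29 replication-dependent histone genes rose together, by a median of 1.91. Better recovery of short single-exon transcripts is argued against as the whole cause by 65 other such coding genes, whose median was 0.19 (bootstrap 95% interval 0.01 to 0.33). That interval resamples genes as if independent and holds no spread between libraries. Of the 65 genes, 10 rose at least 2-fold, against 28 of the 29 histone genes, so a part in the rise is left open. A different split of reads among the 29 histone genes would leave their sum, which rose 4.33 times, unchanged. The list was fixed with 62 genes, and the others had no deposited values. The sum therefore cannot decide on reads shared with those copies. A larger share of cells in S phase may contribute and cannot be told apart from higher transcript levels per cell, since no cell cycle measurement was used here. The median of the DNA replication genes stood only 0.13 above the median gene, against 1.82 for the histone genes.

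The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split alone (1 of 10) gave 11578 genes with limma, 1107 of them changed at least 2-fold, and the highest of the others gave 0 for both, with 62 to 127 genes at an unadjusted p under 0.05 against 11972. The others mix the groups, so the group difference enters the spread within each side, and few called genes follow from that design. Their gene counts therefore do not measure chance. Camera with the preset correlation called 11 lists in the real split (again 1 of 10 as high) and up to 9 in the others. Each mixed split keeps part of the difference between the groups, so list calls there are not a rate of false calls. Their cause was not tested.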
